A study of Mus musculus with 2 samples.

How the data were processed

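Poly(A)-selected RNA of mouse testis was sequenced by the authors in 2 libraries, described in the labels as biological replicates 1 and 2 from male C57BL/6J littermates aged 8 weeks. Per the labels, the RNA was longer than 200 nucleotides, ribosomal RNA was depleted, spike-in RNA was added, and stranded read pairs of 76 nucleotides were made. The labels give both libraries the same donor identifier, so it is not settled whether they came from separate animals. Every p-value, SD and interval below measures only the spread between these samples, the spread among genes or counting error. The labels give 1 group and no treatment, so no test between groups was made.

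Gene and transcript values were used on the mm10 assembly with genome annotation M4, per the deposited readme. Per the file headers, the deposited expected counts are estimated read counts per gene and transcript, computed by the authors from the alignments of 1 replicate to the transcriptome and not normalised. Per the file headers, the authors also scaled them to TPM (transcripts per 1e6) and to FPKM (fragments per kilobase and 1e6 reads). The deposited tables further hold posterior means of counts and TPM, and the percent of a gene's TPM in each transcript as computed by the authors. The deposited interval bounds on TPM were not used. The aligner and the program that assigned reads to transcripts are not given in the sources used here. Each deposited TPM column summed to 1e6 over genes and spike-ins, and FPKM was proportional to TPM. An expected count divides reads that match several genes or transcripts between them, so genes with a near-identical copy have uncertain values.

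The authors' splice junctions and contigs were used as deposited on the older mm9 assembly, per the deposited readme, with both replicates combined. Each deposited junction record holds a read count, equal to the sum of the values named R1 and R2 in all 649521 records. Each deposited contig holds an expression signal and a summed coverage that scales with signal and length. The deposited display score was used only for ranking, with ties ordered by reads or by signal. A deposited fraction per record, not named in the file, was read as the authors' irreproducible discovery rate (IDR) from the file type in the readme. What calls junctions or contigs is not given in the sources used here. No mm9 annotation was used here, so these records carry no gene names, and no coordinate was converted between assemblies.

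The gene tables list 69691 features. Of these, 43346 are Ensembl genes, 97 are spike-in sequences and 26248 have numeric identifiers whose counts are all 0 and were not used. Symbols, positions and gene types came from GENCODE M21 on the same assembly by unversioned identifier. This matched 42462 genes, 21474 of them protein-coding. The 884 unmatched genes held 0.190% and 0.183% of TPM in replicates 1 and 2.

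Genes with a TPM of at least 1 had a median of 767 counts in replicate 1 and 841 in replicate 2. The 10 genes with most counts held 4.55% (95% Wilson interval 4.545 to 4.556) and 5.35% (5.348 to 5.36) of counts. A gene was called detected at a TPM of at least 1 in both libraries. Means are over the 2 libraries, with the SD. Correlations across genes used log2(TPM + 1). Genes are not independent replicates, so these have no p-value. The biological coefficient of variation, the spread between libraries beyond counting, came from edgeR 4.0.16 in R 4.3.3 on rounded expected counts with TMM scaling, for genes with at least 10 counts in both libraries. DESeq2 1.42.0 was the alternative. Log2 ratios of replicate 2 over replicate 1 used TMM-scaled counts with 95% binomial intervals. These intervals, and the Wilson intervals of shares of counts, cover counting error only. A gene with no count in a library was set to a floor of 3 counts there. Its fold at that floor is for expected counts alone, not for posterior means. It leaves out counting error in the other library, so the bound of the 95% interval allows a smaller fold.

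Before the data were examined, 19 gene lists, 24 pairs of paralogs, 10 genes for isoforms and the rule for naming genes were fixed. The rule names the 25 nuclear protein-coding genes with the highest TPM, and the 3 highest and the lowest member of each list with up to 3 members under TPM 1. It also names the paralog pairs, the 10 genes highest in either library by log2 ratio among those with at least 100 counts on average, and the 10 X-linked genes with the highest TPM. For isoforms it takes the 10 fixed genes and the 10 highest genes whose leading transcript holds under 60% of TPM. It ends with the extreme spike-ins and the 5 junctions and 5 contigs of highest score. Other genes named were chosen after their values were seen, and the text says so. Some genes that the rule names, 1 pair among them, are not reported here.

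A list's level was summarised by the median over members of the mean TPM, with its percentile among 10000 random lists of the same size drawn from protein-coding genes. The SD beside a list median is that of the medians of the single libraries, whose mean can differ from the value shown. Where random lists came from detected genes alone, the list still kept its undetected members, which can lower its percentile. Between libraries, the median log2 ratio of members with at least 10 counts in both was placed among 10000 random lists matched on mean expression in 20 bins. The X chromosome was compared with autosomes by a two-sided permutation test over genes with 100000 resamples, and each chromosome with the rest in the same way, with Benjamini-Hochberg adjustment over 21 chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

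The procedures were tested on simulated data. For 19534 genes drawn with a coefficient of variation of 0.15, edgeR returned 0.1496, and 0.166 with 200 genes changed. In simulated libraries of 19521 genes drawn independently of each other, 8 of 200 unshifted lists fell outside the central 95% of random lists. Of 100 lists of 15 genes shifted by 0.2, 0.3 or 0.8 on the log2 scale, 43, 80 and 100 fell outside. A simulated chromosome shifted by -1 among 13735 genes was estimated at -1.12, and 0 of 40 unshifted chromosomes had a p under 0.05.

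Alternatives covered pseudocount, TPM and count minimums, scaling, posterior mean values, random list background, IDR limits and each replicate alone. Added after seeing the data were removal of trends on GC content and length, a filter of 10 counts on average in place of 10 in both libraries, lists without shared members, leading transcripts ranked by counts, and the X chromosome without genes named Gm or Rik. GC content and length were those of the longest M21 transcript and were found for 99.3% of the 19521 genes with at least 10 counts in both libraries. Also added were lists of male duct epithelium, posterior Hox genes, further smooth muscle genes, seminal vesicle, caput epididymis secretion and RNAs without a poly(A) tail.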

Results

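The transcriptome of adult mouse testis was measured as poly(A)-selected RNA in 2 libraries from 8-week-old C57BL/6J males. The testis holds germ cells from spermatogonia through meiotic spermatocytes to round and elongating spermatids, together with Sertoli, Leydig, peritubular, vascular and immune cells. Expected counts summed to 50374324 in replicate 1 and 52788929 in replicate 2, and 25358 and 25235 genes had a count. Mitochondrial genes took 0.636% of counts (95% Wilson interval 0.634 to 0.638) in replicate 1 and 0.942% (0.939 to 0.944) in replicate 2. A gene with no count can hold up to 5.96e-06% of counts in replicate 1 and 5.68e-06% in replicate 2, the share that 3 counts would give.

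Among nuclear protein-coding genes, both libraries were led by genes that package sperm DNA. Tnp2, a transition protein that replaces histones in spermatids, had the highest level, with a TPM of 25658.5 ± 318 (SD, n = 2). Protamine genes Prm2 and Prm1, whose products form the final sperm chromatin, followed at 16217.6 ± 180.5 and 15088 ± 2782 (SD, n = 2). These 3 genes lie together on chromosome 16 of mm10, Tnp2 at 10787936 to 10788660, Prm2 at 10791380 to 10796134 and Prm1 at 10796326 to 10805839. Tnp1, the other main transition protein gene, on chromosome 1 at 73015074 to 73015909, had a TPM of 5222 ± 445 (SD, n = 2). Among all genes the non-coding Rn7sk, named after its value was seen, ranked between Tnp2 and Prm2 at 20999 ± 1672 (SD, n = 2).

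The other genes among the 25 highest included 7 members of the fixed late spermatocyte and elongating spermatid lists, Smcp, Gapdhs, Odf1, Ybx2, Ldhc, Dbil5 and Oaz3. Among the 21 were the sperm glycolysis gene Gapdhs (TPM 3825 ± 3.80), the lactate dehydrogenase gene Ldhc (2911 ± 449), the sperm tail gene Odf1 (3348 ± 29.4), the mitochondrial capsule gene Smcp (3834 ± 159.7), and Tcp11 (3980 ± 425; all SD, n = 2). Insl3, a Leydig cell hormone gene, ranked 6th at 4733 ± 771 and was the only member of the fixed Leydig list among them. The mRNA-binding factor gene Ybx2 (3333 ± 45.0), the selenoprotein gene Gpx4 (3241 ± 183), the polyubiquitin gene Ubb (4831 ± 487) and the tubulin genes Tuba3a (2457 ± 245) and Tubb4b (2281 ± 3.73) were also present. The remaining members were Gsg1, Pebp1, Smim24, Gm15517, Csnk2b, Gstm5, Gm5617, Hrasls5, Dbil5 and Oaz3, between 3663 ± 74.2 for Gsg1 and 1921 ± 106 for Oaz3 (SD, n = 2). These 25 genes held 15.39% and 15.02% of nuclear protein-coding TPM in replicates 1 and 2.

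In all, 15533 of 43346 genes (35.8%) were detected at a TPM of at least 1 in both libraries. Protein-coding genes accounted for 13340, or 62.1% of those annotated, and for 86.9% and 85.6% of TPM. Detected non-coding genes included 544 lincRNA genes, 577 antisense genes and 349 processed pseudogenes. Pseudogene values are uncertain, since their reads can come from the parent gene.

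Levels of the germ cell lists were highest for the latest stages. All 22 elongating spermatid genes were detected, with a median TPM of 1226.5 ± 62.5 (SD, n = 2), from Tnp2, Prm2 and Prm1 down to Hook1 (61.2 ± 6.91), a gene for shaping the sperm head. All 20 round spermatid genes were detected at a median of 218 ± 15.8, led by the acrosome gene Acrbp (1592 ± 124), Dkkl1 (1352 ± 56.3) and the kinase gene Tssk6 (781 ± 71.2), with the acrosomal gene Zpbp lowest at 55.5 ± 5.62. The 12 late spermatocyte genes had a median of 133 ± 28.005, from Ybx2, Ldhc and the chaperone gene Hspa2 (690.4 ± 69.5) down to the transcription factor gene Mybl1 (6.53 ± 2.74). Each of these 3 medians exceeded at least 99.99% of random lists in each library.

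Genes of meiotic chromosomes were lower, with 27 of 28 measured members detected and a median TPM of 12.8 ± 1.40 (SD, n = 2). The synaptonemal complex genes Syce1 (234 ± 19.3) and Syce3 (204 ± 14.8) and the cohesin gene Stag3 (187 ± 17.4) led, and Mei4, a gene for making meiotic breaks, was at 0.120 ± 0.0141. Spermatogonial genes had a median of 6.23 ± 0.290 with 16 of 18 detected. Dmrtb1, a regulator of meiotic entry, stood far above the other spermatogonial genes at 886 ± 124, followed by Uchl1 (72.5 ± 3.68) and Id4 (28.6 ± 3.51). The stem cell genes Ret (0.540 ± 0.113) and Nanos2 (0.0900 ± 0.0141) were under a TPM of 1. The meiotic median was at the 98.3 percentile of random protein-coding lists and the spermatogonial median at the 74.5 percentile. Against detected protein-coding genes alone these percentiles were 48.7 and 5.46.

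Lists for germ cell pathways were also high. The piRNA pathway, which silences transposons in germ cells, had 19 of 20 genes detected and a median TPM of 47.8 ± 2.54 (SD, n = 2), with Mael (633 ± 54.6), Piwil1 (216 ± 9.13) and Tdrd6 (167 ± 6.49) highest and Piwil4 at 0.535 ± 0.0778. Axoneme genes, which build the sperm tail, had 17 of 18 detected and a median of 129 ± 7.18, led by Ropn1l (1349 ± 112), Rsph1 (509 ± 23.3) and Tekt2 (449 ± 14.8). The radial spoke gene Rsph4a was at 0.0850 ± 0.0212. Both medians lay above all 10000 random lists, and the piRNA median was at the 99.6 percentile against detected genes alone.

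The fixed histone lists differed in level. All 6 replacement histone genes, expressed outside S phase, were detected at a median TPM of 179 ± 20.3 (SD, n = 2), with H2afz (763 ± 128), H3f3a (473 ± 10.1) and H3f3b (265 ± 38.8) highest and H1f0 lowest (8.32 ± 1.12). Of 10 replication-dependent histone genes, 7 were detected at a median of 4.16 ± 0.615, with Hist1h4a (77.8 ± 7.80), Hist1h4c (56.6 ± 0.622) and Hist1h3a (27.5 ± 2.98) highest. Hist1h1e (0.570 ± 0.368), Hist1h1b (0.160 ± 0.226) and Hist1h1d at 0.05 in both libraries were under a TPM of 1. The medians were at the 99.97 and 52.4 percentiles of random lists. Hist2h2aa1, a histone gene in neither list and named after its value was seen, had a TPM of 1062 ± 152 (SD, n = 2), above H2afz. The difference between the lists therefore holds for the listed members only. Messenger RNAs of replication-dependent histones mostly lack a poly(A) tail, and their near-identical copies make single values uncertain.

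Somatic cells of the testis were represented by every list. Sertoli genes had 18 of 20 detected and a median TPM of 16.5 ± 1.44 (SD, n = 2), led by the secreted protein gene Clu (1359 ± 234), the inhibin gene Inha (162 ± 27.9) and Cst12 (137 ± 48.3). The growth factor gene Gdnf was lowest at 0.480 ± 0.0849. All 13 Leydig genes were detected at a median of 27.8 ± 5.82, with the steroid enzyme gene Cyp17a1 (166 ± 24.6) and the lipoprotein receptor gene Scarb1 (157 ± 7.31) after Insl3, and Lhcgr lowest (2.56 ± 0.170). All 11 peritubular and stromal genes were detected at a median of 12.7 ± 6.41, led by the smooth muscle actin gene Acta2 (136 ± 62.6), Dcn (30.04 ± 10.9) and Tagln (28.6 ± 19.4), with Lum lowest (1.81 ± 0.608).

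Macrophage genes had 9 of 11 detected and a median TPM of 3.58 ± 0.742 (SD, n = 2), with the complement genes C1qb (17.3 ± 1.35) and C1qc (8.68 ± 1.08) and the lysozyme gene Lyz2 (12.9 ± 1.94) highest. Ptprc (0.430 ± 0.127) and Cd163 (0.15 ± 0.0141) were under a TPM of 1. Endothelial genes had 9 of 10 detected and a median of 2.81 ± 0.106, from Egfl7 (30.1 ± 9.12), Vwf (14.0 ± 0.955) and Cldn5 (8.12 ± 0.283) to Tek (0.900 ± 0.311). Among 7 red blood cell genes 5 were detected, at a list median of 24.9 ± 0.389, and the globin genes Hba-a2 (79.8 ± 5.10), Hbb-bs (58.1 ± 7.81) and Hba-a1 (35.7 ± 0.544) led. The anion exchanger gene Slc4a1 was lowest at 0.00500 ± 0.00707. Medians of the Sertoli, Leydig, peritubular, macrophage, endothelial and red blood cell lists were at the 98.5, 99.2, 90.3, 50.04, 38.8 and 95.3 percentiles of random lists. Against detected genes alone, these percentiles were 69.7, 91.1, 48.5, 1.14, 0.25 and 81.2.

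Genes of other organs were low. Only 4 of 16 were detected, at a list median TPM of 0.278 ± 0.148 (SD, n = 2) and the 1.37 percentile. The highest were the glutamate transporter gene Slc17a7 (27.1 ± 0.0566), the apolipoprotein gene Apoa2 (7.15 ± 0.297) and the skeletal muscle actin gene Acta1, which had a TPM of 13.3 in replicate 1 and 0.660 in replicate 2. Myh4 was lowest at 0.0250 ± 0.00707. The epididymis list had 1 of 11 genes detected, Rnase10 at 2.83 ± 0.573, and a median of 0.0550 ± 0.0283 at the 0.470 percentile. In that list Crisp1, which encodes a secreted protein of the epididymis, had a TPM of 454 in replicate 1 and 0.2 in replicate 2. Rnase9 was at 0.900 and 0.0200. The genes Lcn10, Spag11b and Ovch2 had no counts in either library.

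Housekeeping genes were all detected, at a median TPM of 430.2 ± 10.2 (SD, n = 2), with Eef1a1 (1814 ± 31.0), Eef2 (1322 ± 124) and Rplp0 (1285 ± 18.8) highest and the X-linked gene Hprt lowest (4.42 ± 1.29). Of 13 Y-linked genes, 5 were detected, at a list median of 1.11 ± 0.332 and the 16.5 percentile. In replicate 2 alone 9 were detected, and in replicate 1 alone 6. Eif2s3y (12.8 ± 2.25), Uba1y (9.31 ± 0.410) and Ssty2 (6.63 ± 1.10) were highest and Rbmy lowest (0.0250 ± 0.0354). Ssty2, Sly and Rbmy belong to multicopy families, so their values are uncertain. Over all 19 lists, 233 of 278 measured members were detected.

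**Figure D1:**
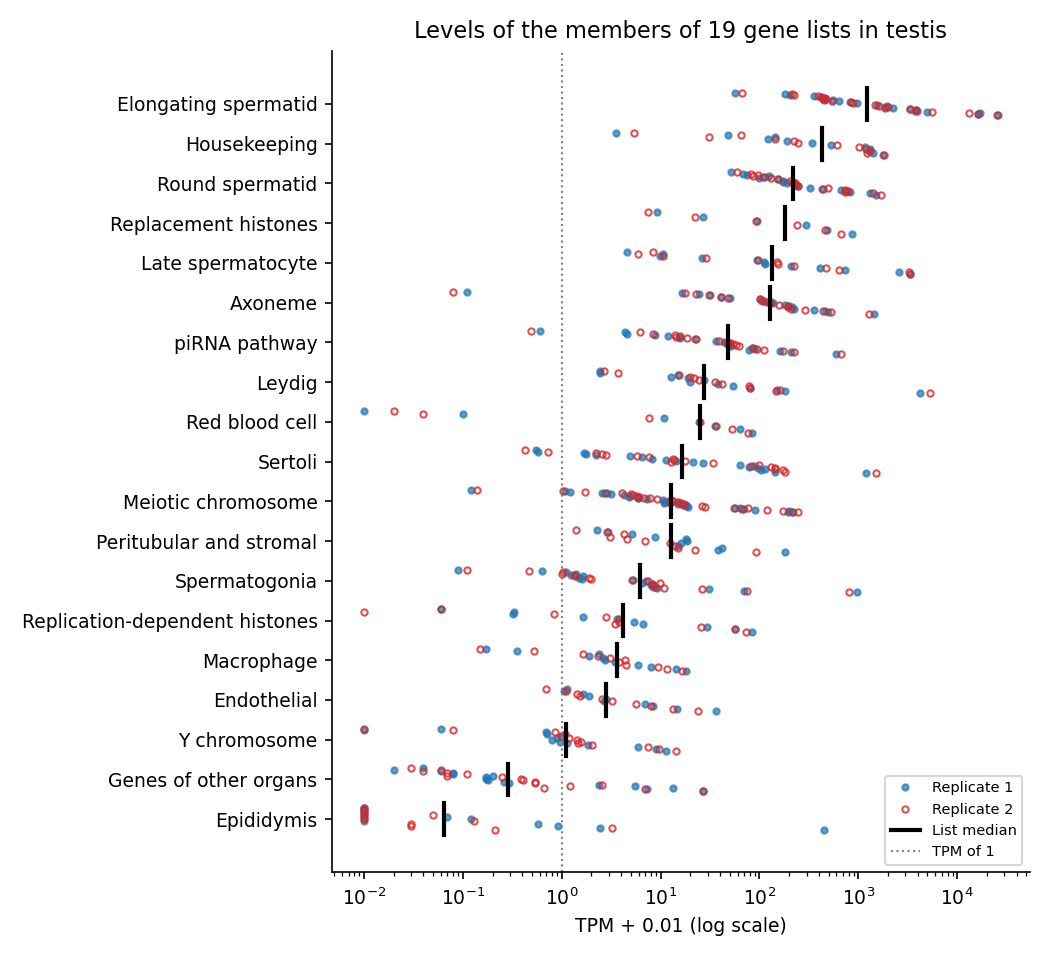
TPM of each member of the 19 gene lists on a log scale after adding 0.01, with filled points for replicate 1, open points for replicate 2, and a bar at the list median. Elongating spermatid genes have the highest median at 1226.5, and Crisp1 in the epididymis list stands at 454 in replicate 1 against 0.2 in replicate 2.

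Agreement of the libraries was compared next. Across 43346 genes, log2(TPM + 1) correlated with a Pearson r of 0.991 and a Spearman rho of 0.959. Among the 15533 detected genes the median absolute log2 ratio was 0.17, and 246 (1.58%) differed by more than 2-fold, 147 of them higher in replicate 1 and 99 higher in replicate 2. The biological coefficient of variation was 0.183 over 19534 genes. A chi-square of 41.5 per gene over 21774 genes was above sampling noise, so the files are not 1 library deposited again. This does not tell whether the animals differed.

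The largest differences towards replicate 1 were found in these genes. Crisp1, for a secreted protein of the epididymis, at 40293758 to 40319207 on chromosome 17, had 22264.9 counts in replicate 1 and 10 in replicate 2, a log2 ratio of -11.13 (95% counting interval -12.26 to -10.32). The protease inhibitor gene Spink8 had 3698 and 5 counts, a log2 ratio of -9.47 (-11.23 to -8.38). Akr1b7, an aldo-keto reductase gene, had 2482 and 3 counts, a log2 ratio of -9.55 (-12.05 to -8.22). By expected counts, with none in replicate 2, folds towards replicate 1 at the floor of 3 counts were 540.3 for Wfdc15b, 366 for the lactoferrin gene Ltf and 318 for Adam7. They were 266 for the defensin gene Defb28, 148 for the cyclooxygenase gene Ptgs2 and 139.6 for Spink10. The 95% counting intervals allowed smaller folds, with log2 ratios of up to -8.78 for Wfdc15b and -6.82 for Spink10. By posterior mean TPM the differences were smaller for some. Spink10 had 26.4 and 2.96, Ptgs2 2.62 and 0.16, Wfdc15b 104.7 and 0.22, Defb28 95.3 and 0.12, Adam7 6.95 and 0.03, and Ltf 10.06 and 0.01.

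The 10 genes with the largest log2 ratios towards replicate 2 were mostly non-coding. Gene types were not tallied over all genes higher in replicate 2. The 10 included the antisense gene Slfn5os with 1 and 374 counts (log2 ratio 7.89, 5.98 to 13.78), the antisense gene 4930533I22Rik (3.72, 3.395 to 4.07) and the lincRNA gene 4930408O17Rik (2.58, 2.23 to 2.97). Ugt1a6b (2.78), a member of a gene cluster with shared exons, and the pseudogenes Gm12191 (4.76), Gm6472 (3.85), Gm7278 (3.59) and Gm10093 (2.71) have uncertain values for shared sequence. Gm29089 on the Y chromosome had no count in replicate 1 and 385.7 in replicate 2, 122-fold by expected counts at the floor of 3 counts. Its posterior mean TPM was 9.95 and 22.1. On chromosome 3, the lincRNA gene Gm26553 had 463 and 0 counts and the nearby lincRNA gene Gm26689 had 0 and 412. By posterior mean TPM the pair was less apart, with 5.72 and 1.86 for Gm26553 and 1.35 and 4.18 for Gm26689. This comparison has 1 library on each side and no replicate check.

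Cell type lists also differed between the libraries. Peritubular and stromal genes were lower in replicate 2 in 11 of 11 cases, with a median log2 ratio of -0.77 that lay below all 10000 matched random lists. Acta2 had a log2 ratio of -0.998, Tagln -1.53 and Dcn -0.77, and Cnn1, named after its value was seen, -2.00. Sertoli genes were higher in replicate 2 in 17 of 20 cases with a median of 0.33, above all random lists. Meiotic chromosome genes were higher in 23 of 28 (median 0.26, percentile 99.99), piRNA pathway genes in 17 of 20 (0.14, percentile 99.3), round spermatid genes in 16 of 20 (0.09, percentile 99.7) and Y-linked genes in 10 of 11 (0.30, percentile 98.4). These 6 of 18 tested lists lay outside the central 95% of random lists, where chance would give 0.9 if genes varied independently. Genes of a list can move together between samples, and 1 library stood on each side. The excess over 0.9 therefore does not show more than ordinary variation between samples.

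Median log2 ratios of the other tested lists lay inside the central 95% of random lists. They were 0.03 for spermatogonia, 0.09 for late spermatocytes, -0.05 for elongating spermatids, 0.11 for Leydig cells, -0.14 for macrophages, -0.20 for endothelial cells and -0.17 for red blood cells. For other organs, axoneme, replication-dependent histones, replacement histones and housekeeping genes they were 0.05, -0.10, -0.24, -0.13 and -0.02. In the list of other organs the skeletal muscle genes Acta1 and Ckm, named after their values were seen, had log2 ratios of -4.34 and -2.20. In the housekeeping list B2m, a part of class I antigen complexes named after its value was seen, had a TPM of 145 in replicate 1 and 31.0 in replicate 2. With trends on GC content and length removed, the Y list moved to 0.07 (percentile 74.0), replacement histones to -0.25 (percentile 0.120), meiotic chromosome genes to 0.15 (percentile 99.8) and Leydig genes to 0.04 (percentile 70.8). Against random lists not matched on expression, round spermatid and piRNA genes were at the 86.2 and 94.5 percentiles.

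**Figure D2:**
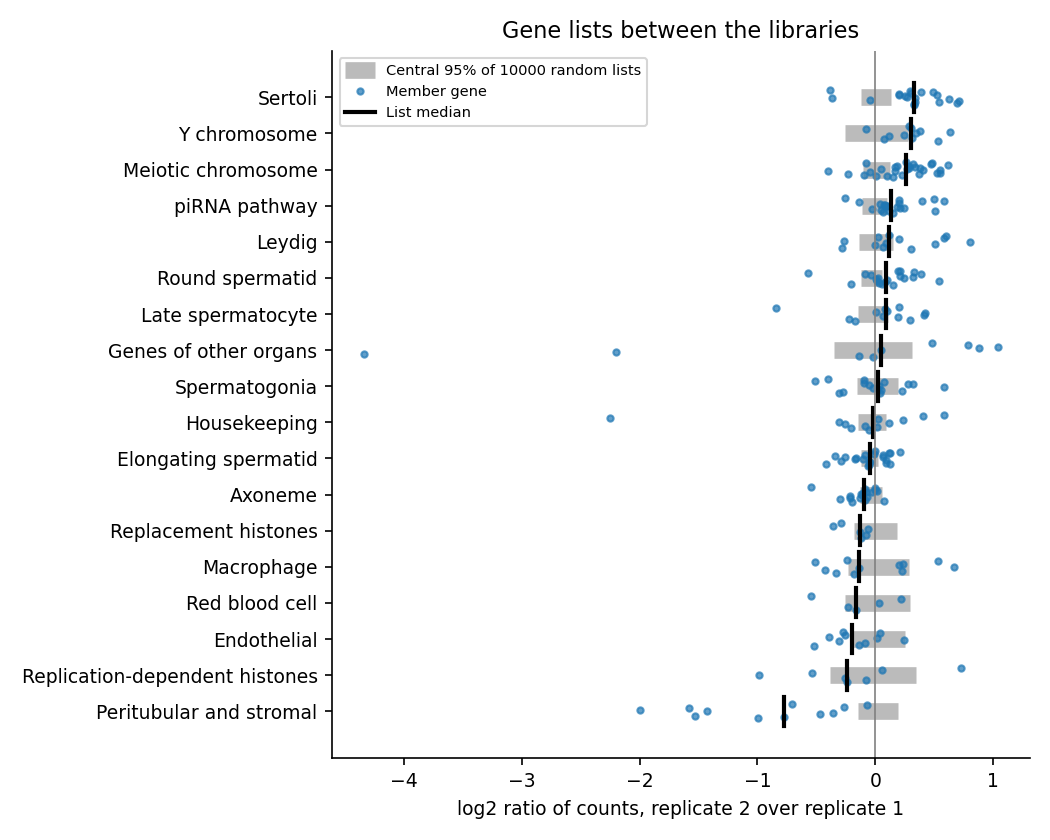
Log2 ratio of TMM-scaled counts in replicate 2 over replicate 1 for members of 18 lists, with points for genes, bars for list medians and grey bands for the central 95% of 10000 random lists matched on expression. The peritubular and stromal median is at -0.77 and the Sertoli median at 0.33.

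Ribosomal and mitochondrial transcripts differed as well, in genes chosen after their values were seen. Gm42418, a non-coding gene on chromosome 17 at 39846958 to 39848788 in a region of ribosomal RNA sequence, had a TPM of 6702 in replicate 1 and 14535 in replicate 2. It took 0.875% of counts (95% Wilson interval 0.872 to 0.877) in replicate 1 and 1.88% (1.88 to 1.89) in replicate 2. The mitochondrial ribosomal genes mt-Rnr1 and mt-Rnr2 had log2 ratios of 1.43 and 0.85. Among mitochondrial protein-coding genes 10 of 13 were higher in replicate 2, from mt-Nd6 at 1.05 to mt-Nd4l at -0.20.

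X-linked genes were expressed at lower levels than autosomal genes. In male meiosis the X chromosome is silenced, which makes it a natural comparison in this tissue. Among protein-coding genes with a mean TPM of at least 1, the median was 4.96 for 532 X-linked genes and 12.7 for 13203 autosomal genes. The difference in median log2 TPM was -1.36 (two-sided permutation test over genes, p = 1e-05, the smallest that 100000 resamples can give). Detection was also lower, at 496 of 941 X-linked genes (52.7%, 95% Wilson interval 49.5 to 55.9) against 12795 of 20337 autosomal genes (62.9%; Fisher's exact test, two-sided, odds ratio 0.657, p = 5.04e-10).

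The highest X-linked gene was Akap4, which anchors signalling in the sperm tail sheath, at 7067519 to 7078609, with a TPM of 455 ± 19.02 (SD, n = 2). It was followed by Tsga8 (237 ± 28.7), Hypm (224 ± 49.1), Cypt1 (217 ± 49.1) and Gm5941 (180.4 ± 24.9). Cypt3 (139 ± 25.7), Prdx4 (137 ± 26.4), Ndufa1 (136 ± 1.07), Ctag2 (132 ± 30.2) and Asb9 (125 ± 4.55) completed the 10 highest. Of 21 chromosomes each set against the rest, 9 had an adjusted p under 0.05 by permutation with Benjamini-Hochberg adjustment. Genes of chromosomes 5, 7, 11 and 17 were higher, by 0.26, 0.30, 0.31 and 0.36 on the log2 scale. Those of chromosomes 13, 14, 18, X and Y differed by -0.56, -0.52, -0.48, -1.35 and -2.61. The test treats genes as independent, although neighbouring and duplicated genes are not.

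**Figure D3:**
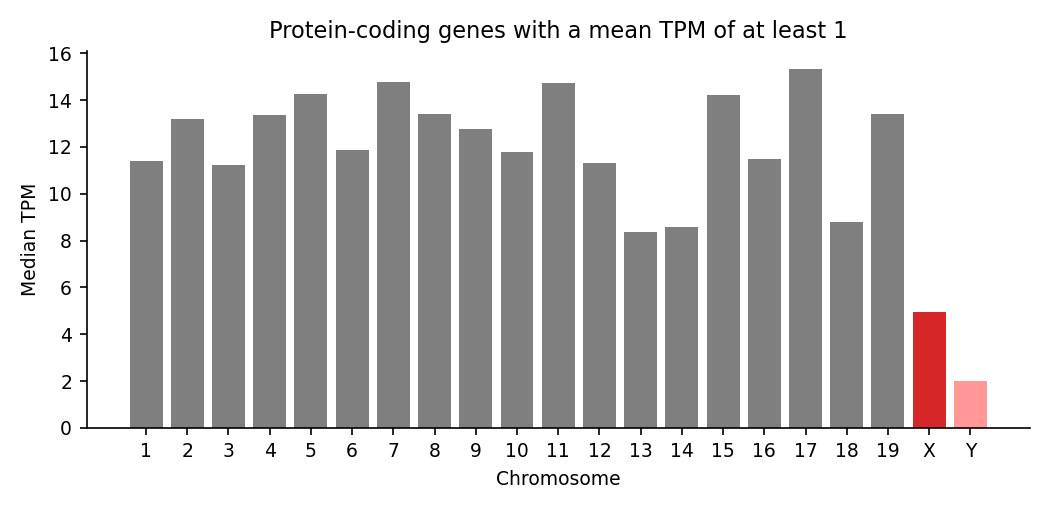
Median TPM of protein-coding genes with a mean TPM of at least 1 on each chromosome, as bars from 0. Chromosome X stands at 4.96, below every autosome, of which chromosome 13 is lowest at 8.36, and Y at 2.00 (41 genes).

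Germ cells use their own copies of many widely expressed genes. The first gene of each pair was listed beforehand as testis-enriched. No other tissue was measured, so this label was not tested, including for the Y-linked Eif2s3y and Ddx3y. The first member was higher in both libraries in 20 of 24 pairs. The 3 largest ratios belonged to autosomal copies of X-linked genes, with log2 ratios of (TPM + 1) of 6.79 ± 0.50 for the glycerol kinase genes Gk2 over Gk, 5.61 ± 0.18 for the centrin genes Cetn1 over Cetn2, and 5.30 ± 0.05 for the glycolytic genes Pgk2 over Pgk1 (SD, n = 2). Such pairs with smaller ratios were Pdha2 over Pdha1 (4.20 ± 0.24), Rbmxl2 over Rbmx (3.29 ± 0.40), Rpl10l over Rpl10 (1.28 ± 0.55) and Utp14b over Utp14a (0.27 ± 0.18). Rpl10l had a TPM of 239 ± 0.552 and Rpl10 of 101 ± 37.8.

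The other pairs with a higher first member included genes of energy metabolism and cell structure. Ratios were 4.81 ± 0.29 for Tuba3a over Tuba1a, 4.48 ± 0.35 for Cox6b2 over Cox6b1, 4.18 ± 0.05 for Ppp3r2 over Ppp3r1, 4.04 ± 0.22 for the cytochrome c genes Cyct over Cycs, 3.86 ± 0.04 for Ppp1cc over Ppp1ca and 3.72 ± 0.35 for Gapdhs over Gapdh (SD, n = 2). Smaller ratios were found for Ppp3cc over Ppp3ca (1.76 ± 0.34), Ldhc over Ldha (1.73 ± 0.21), Taf7l over Taf7 (1.70 ± 0.10), Eif2s3y over Eif2s3x (1.64 ± 0.27), Hspa2 over Hspa8 (0.91 ± 0.01) and Pfn3 over Pfn1 (0.59 ± 0.12). The second member was higher for Ddx3y over Ddx3x (-1.42 ± 0.12), Tbpl1 over Tbp (-0.41 ± 0.12) and Actl7b over Actb (-0.04 ± 0.002). For Slc25a31 over Slc25a4 the libraries had opposite signs, -0.20 and 0.21. No test was made on single pairs, and reads shared between paralogs make these ratios uncertain.

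**Figure D4:**
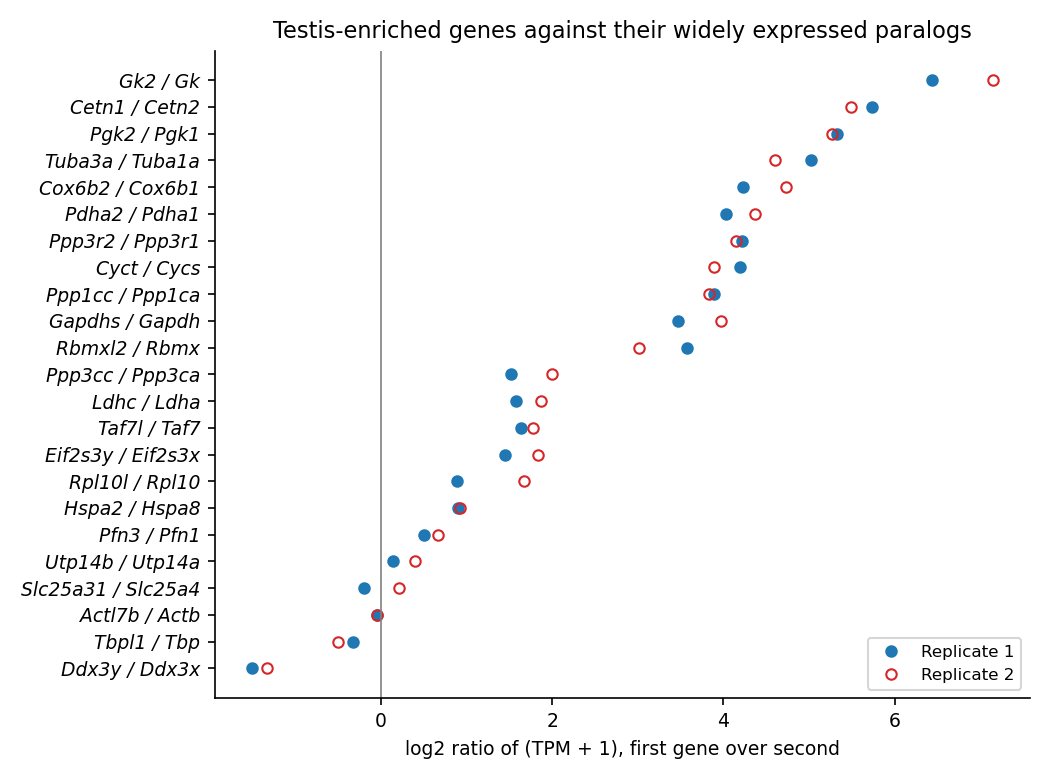
Log2 ratio of (TPM + 1) of the first gene of each pair, listed beforehand as testis-enriched, over its paralog, with filled points for replicate 1 and open points for replicate 2. Values reach 6.79 on average for Gk2 over Gk and -1.42 for Ddx3y over Ddx3x.

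Transcript shares were described in both libraries for the genes fixed beforehand. Whether the named transcripts are particular to testis was not tested. Ace-202, the short angiotensin-converting enzyme transcript of 2418 nucleotides that starts inside the gene at 105975208 on chromosome 11, held 86.0% ± 0.167 of the gene's TPM (SD, n = 2). The full-length Ace-201, starting at 105967945, held 5.74% ± 0.000499. The hexokinase transcript Hk1-202 held 42.2% ± 0.653, Ppp1cc-201 of the phosphatase gene held 69.9% ± 2.24, and Adcy10-202 of soluble adenylyl cyclase held 53.5% ± 2.85. The transcripts Kit-201 and Kit-204 had 50.4% and 49.6%, both ± 0.106. In the deposited annotation M4, Prkaca, Piwil1 and Tnp2 have 1 transcript each, so other isoforms of these genes could not be measured.

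Short annotated transcripts had the highest mean TPM in some genes. Crem-238, a processed transcript of 290 nucleotides, held 62.6% ± 0.442 of TPM of the spermatid transcription factor gene Crem but 14.0% ± 0.280 of its counts (SD, n = 2). Odf2-220 of 349 nucleotides held 30.8% ± 5.39 of Odf2 TPM and 3.82% ± 0.958 of counts, against 29.2% ± 0.342 and 53.8% ± 2.33 for Odf2-201 of 2376 nucleotides. In replicate 2, Odf2-201 led by TPM at 29.4% against 27.03%. Tcp11-204, at 587 nucleotides, held 45.9% ± 1.35 of Tcp11 TPM and 18.7% ± 0.342 of counts. Among other highly expressed genes with a split output, shares of the transcript with the highest mean TPM were 58.7% ± 2.38 for Ubb-201, 49.9% ± 0.478 for Gapdhs-201, 35.5% ± 4.84 for Ybx2-205, 56.9% ± 2.49 for Phkg2-201 and 41.4% ± 2.60 for Cox6b2-201. They were 48.8% ± 6.67 for Rpl41-201 and 47.3% ± 1.71 for Rnaseh2a-209. The leader changed between libraries in 3 of these genes. Ybx2-204 led in replicate 2 (41.95% against 32.1% for Ybx2-205), Cox6b2-206 in replicate 1 (41.04% against 39.5% for Cox6b2-201) and Rpl41-203 in replicate 1 (49.5% against 44.1% for Rpl41-201). By mean share of counts, Rnaseh2a-209 held 27.4% against 35.2% for Rnaseh2a-210, and Ybx2-205 held 39.6% against 40.9% for Ybx2-201.

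The same transcript led in both libraries in 9358 of 10591 genes with several transcripts (88.4%, 95% Wilson interval 87.7 to 89.0). Over all 10591 genes, the median share of the leading transcript was 69.2%, with 2460 genes over 90% and 3929 under 60%. Where the leading transcript differed, its median share was 47.5%. Of 8685 protein-coding genes with a shared leading transcript, that transcript was itself protein-coding in 7534, a processed transcript in 462, a retained intron in 378 and a target of nonsense-mediated decay in 221. Shares from short reads rest on how reads were divided among overlapping transcripts.

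Spike-in RNAs gave a measure of technical spread. Of 96 ERCC sequences, 71 had an expected count above 0 in both libraries and 18 had none in either. At the TPM of at least 1 in both libraries used for genes, 57 were detected. Spike-ins took 2.68% of counts (95% Wilson interval 2.678 to 2.687) in replicate 1 and 2.51% (2.502 to 2.511) in replicate 2. ERCC-00018 was highest at a TPM of 6448 ± 82.7 (SD, n = 2), while ERCC-00147, ERCC-00157 and ERCC-00168 were lowest, with 1 count each in 1 library. Log2 values correlated with an r of 0.998 over 62 spike-ins. The SD of log2 ratios between libraries was 0.20 over 44 spike-ins with at least 100 counts and 0.31 over 14458 genes with at least 100 counts.

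The splice junction list on mm9 held 649521 junctions with 45021975 reads. The 5 leading junctions were at 10796627 to 10796718 on chromosome 16 with 275733 reads, 10791728 to 10791832 on chromosome 16 with 104574, and 125232997 to 125235985 on chromosome 6 with 73884. They were followed by 54117266 to 54121778 on chromosome 7 with 70591 and 73061900 to 73062298 on chromosome 1 with 68113. Junctions with a single read made up 39.7%, and the 41.8% with reads in both R1 and R2 held 98.6% of reads. At an IDR of at most 0.1, 206043 junctions (31.7%) remained with 98.1% of reads. Chromosome X held 2.41% of junctions and 0.849% of reads.

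The contig list on mm9 held 1057671 stretches of continuous transcription covering 367.9 Mb. At an IDR of at most 0.1 there were 516140 contigs over 292.5 Mb with 99.2% of summed coverage. The highest signal, 8340 in the authors' units, was on chromosome 16 at 11143991 to 11144488. The next were on chromosome 17 at 39979936 to 39985774 (3320.0), chromosome 9 at 110183747 to 110183883 (3300.0), chromosome 3 at 5860319 to 5860829 (3210.0) and chromosome 9 at 78023110 to 78023433 (2930.0). The contig on chromosome 17 alone held 1.98% of summed coverage. Chromosome X held 2.08% of contigs and 0.954% of summed coverage.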

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

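No paired analysis was possible because the labels give 1 group of 2 samples. Of the alternatives, 5 were chosen after seeing the data: GC and length trends removed, a filter on mean counts, lists without shared members, leading transcripts by counts, and the X chromosome without genes named Gm or Rik. The difference of X from autosomes kept its sign and its side of the threshold in all 8 alternatives, from -0.84 to -1.77. Pairs with the first member higher numbered 19 to 21, and lists apart between the libraries 4 to 6 of the 18 tested. With the filter on mean counts the epididymis list could also be tested and lay outside, which makes 7 of 19. Correlation of the libraries ranged from 0.986 to 0.991. Detected genes ranged from 10462 at a TPM of at least 5 to 20985 at 0.1.

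Values over all genes or lists that were called moved were these. The limit for this call differed by kind of result and was wider for numbers of genes than for shares. Detected genes were therefore not called moved, although they ranged from 10462 to 20985. The coefficient of variation was 0.211 with genes of at least 1 count, a setting that adds genes with few counts. The share of genes with the same leading transcript was 91.2% at a gene TPM of at least 10, 84.3% with no minimum, 87.6% by posterior mean TPM, 97.1% where the leading share was at least 60%, and 91.9% ranked by expected counts. Junctions numbered 206043 at an IDR of at most 0.1, 157719 at 0.01 and 391471 at or above the median score. Contigs numbered 516140, 331953 and, at 200 bases or longer, 546404. These junction and contig numbers fall by the construction of each filter, and for the other values the cause was not tested. In single lists, Y-linked genes detected moved from 5 to 9 without replicate 1, 11 at a TPM of at least 0.1 and 3 at 5, and other organs from 4 to 10 at 0.1 and 2 at 5. Epididymis moved from 1 to 2 or 0. At a TPM of at least 5, spermatogonia, peritubular, macrophage, endothelial and replication-dependent histone counts moved to 10, 6, 3, 4 and 3. Percentiles were called moved against detected genes for 14 of 19 lists. The size of the change varied, with late spermatocytes from 100 to 99.99 and spermatogonia from 74.5 to 5.46.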

Other observations

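The tests on Leydig, caput, mitochondrial and unpolyadenylated genes, and the filter on mean counts, were chosen after their results were seen. The tests on duct epithelium and on GC content were set before their results, though after the patterns. No difference between biological groups was tested, because the labels give 1 group.

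Between the libraries, X-linked genes as a class were higher in replicate 2. Among 707 X-linked protein-coding genes with at least 10 counts in both, 74.4% were higher in replicate 2, with a median log2 ratio of 0.25, against -0.01 for 15576 autosomal genes. Transcripts of low GC content were higher in replicate 2 too, with a Spearman correlation of -0.415 between GC content and log2 ratio across 19375 genes. The 10% of genes with the lowest GC content, up to 41.3%, had a median log2 ratio of 0.26, and the 10% with the highest, from 57.8%, one of -0.19. Length had little relation to the ratio (0.0446). Ranking transcripts by TPM or by counts chose different leading transcripts in 1917 genes (18.1%) in replicate 1, where the median length was 733 nucleotides by TPM and 3451 by counts.

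Replicate 1 held Crisp1, Spink8, Akr1b7, Wfdc15b, Defb28 and Adam7, which are known from the epididymis and vas deferens, together with more smooth muscle RNA. A candidate explanation is tissue of the male ducts in that sample. A list of 22 duct epithelium genes had a median log2 ratio of -0.92, below all 10000 random lists but short of the -1 set beforehand, with 13 of 17 tested members lower in replicate 2. That filter of 10 counts in both libraries drops members lost in replicate 2, and with 10 counts on average the median was -1.09 over 21 members, so the bound is passed only under a filter chosen later and the question stays open. The testis itself had 10 of the 22 at a TPM of at least 1 in replicate 2; the most abundant, Spint2, was at 115.5 and 100.3, while Krt19 was at 8.96 and 0.650. Caput epididymis secretion genes summed to a TPM of 0.730 in replicate 1, far under the 454 of Crisp1. Gpx5 among them had 33 counts in replicate 1 and 1 in replicate 2. The caput rule was set after these values were seen, so caput tissue was not excluded. A plain loss of tubule cells in replicate 1 would lower the median log2 ratios of the other cell lists alike. The Leydig median was 0.11 (0.04 with GC and length trends removed) against a stromal median of -0.77 (-0.998), so these lists did not move alike. Endothelial, red blood cell and macrophage medians were below 0, at -0.20, -0.17 and -0.14, though inside the random lists. The Leydig rule was set after its value was seen, so a loss of tubule cells was not excluded.

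Other lists bear on the same pattern as values. Further smooth muscle genes had a median log2 ratio of -0.84 with 10 of 11 lower in replicate 2, below all random lists. Posterior Hox genes with 10 counts on average had a median of -0.85 at the 0.08 percentile, with 9 of 10 lower in replicate 2. The filter of 10 counts in both libraries left 7 of the Hox genes at -0.23 (percentile 19.1), since it drops Hoxa10, Hoxa11 and Hoxb7, which had under 10 counts in replicate 2. The fixed epididymis list, testable only with the filter on mean counts, had a median of -4.62, below all random lists, with 3 of 4 members lower in replicate 2, though Crisp1 is one of the genes that define the pattern. Seminal vesicle genes had 1 member with enough counts and summed to a TPM of 3.32 and 3.97. The skeletal muscle genes Acta1 and Ckm were also lower in replicate 2, with log2 ratios of -4.34 and -2.20, and muscle outside the ducts was not tested as a source.

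Gm42418 and mitochondrial RNAs were higher in replicate 2. If poly(A) selection had been weaker in that library, other RNAs without a tail would be higher by a like amount, but 12 such RNAs had a median log2 ratio of -0.0761 (SD among members 0.586), against 1.10 for Gm42418. The part of this rule that weighs the SD was added after the value was seen and did not change its outcome. Carry-over of cytoplasmic ribosomal RNA alone would leave mitochondrial messengers unchanged, and their median was 0.59. A large part of the list without a tail was histone messengers, and all of these but Hist1h3b were lower in replicate 2. Of the other tested members, Rn7sk, Rmrp and Rpph1 were higher, at 0.09, 0.41 and 0.82. Terc, Scarna2 and Snord17 were lower, at -0.08, -0.01 and -1.39. No tested member reached the 1.10 of Gm42418, but the median rests partly on histones, and a smaller weakening of selection was not excluded. A difference in ribosomal RNA depletion together with another change could account for both and was not tested.

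Sertoli, meiotic and piRNA lists were higher in replicate 2, and GC content and length trends between the libraries could produce such shifts. With these trends removed, all 3 lists still lay outside the random lists (3 of 3), with medians of 0.42, 0.15 and 0.14, against 0.33, 0.26 and 0.14 before. This argues against the trend as the whole cause, although the meiotic median became smaller. The Y list, by contrast, moved from 0.30 to 0.07. A difference in the share of these cells between the samples stays open, and no cell counts were used here.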
